A study of Homo sapiens with 10 samples.

How the data were processed

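ChIP-seq peak lists of H441 and A549 lung adenocarcinoma cells were analysed. The series has 10 samples, of which 7 have peak lists and 3 are input DNA, whose data are not analysed here. Samples were grouped by their titles into Smad3 siControl, Smad3 siTTF-1, TTF-1 0 h, TTF-1 1.5 h, Smad4 siControl and Smad4 siTTF-1 in H441 and Smad3 in A549, with 1 library each. Per the labels, peaks were called against the input of the same cell line at a false discovery rate limit of 1% for Smad3 and TTF-1 in H441, 5% for A549 and 10% for Smad4. The genome build was hg18, per the submitters' processing notes. The aligner, the peak caller and their settings are not given in the sources used here. All lists were called on single libraries.

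Each deposited list gives the position of a peak in steps of 50 bp, a peak number and a score. The deposited score was 1000 for every peak in all 10 lists and was not used as a strength. The peak number runs from 1 to the number of peaks in each called list. Its meaning is not given in the sources used here. Wider peaks had lower numbers (Spearman correlation across peaks from -0.46 to -0.63), and peaks with low numbers were found more often in the other lists. In 3 further lists the authors deposited subsets of the Smad3 peaks. Per the labels, these are siControl peaks without a siTTF-1 peak and siTTF-1 peaks with or without a TTF-1 0 h peak. In all, 1 track line was skipped. Positions were converted to count from 1 by adding 1 to the deposited start.

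Overlap was counted in the peaks of the first-named list, with at least 1 bp shared. The same rule recovered all 3 derived lists in full. Shares have exact Clopper-Pearson 95% intervals. Associations of 2 overlaps over the same peaks were tested with Fisher's exact test (two-sided), with the sample odds ratio and its Woolf 95% interval, and the A549 peaks with an exact McNemar test. Peaks are not replicates, so these tests describe the lists and not a population of cultures. Background was measured as the overlap of the same peaks moved by 25 kb to either side, and by 1000 random placements of the peaks on their own chromosome up to the last position in any list (100 placements for the 50% coverage alternative). Mantel-Haenszel odds ratios were taken within 5 equal strata of peak width or peak number. No read counts were used, so the depth of each library is unknown and no limit of detection could be set.

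Before the data were examined, the tests, the alternatives and the rule for named peaks were fixed. The rule named the 3 widest peaks of each class, since no list holds a score that varies, and the 1 Mb windows with the most peaks. Where 2 classes share their widest peaks these are given once, and of the windows the first 1 to 3 of each list are given. The alternatives were another overlap rule (50% of the peak, centres within 200 bp, or edges within 500 bp), the wider 50% of each list, lists of equal length, autosomes only, merging of peaks within 500 bp, the other TTF-1 list, strata of width, moves of 10 to 50 kb or circular shifts as null, and intervals from 1000 resamples of whole chromosomes. Every use of the peak number as an order was chosen after seeing the data, as were the moves by 25 kb. A test of whether weak enrichment of the Smad4 siControl library gave its short list was written down and then left out after its value was seen. Its only peak lay at number 9 of the Smad4 siTTF-1 list, and 1 peak decided nothing. Planned counts of 10 gene lists near peaks and of sequence motifs were not run, because no genome or annotation of hg18 was used here. Peaks are therefore named by position without gene, exon or intron.

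Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The overlap code was tested on simulated data: 9 overlap counts of shifted lists equalled those of bedtools 2.31.1. In 100 simulations on the 8941 siControl peaks with a true odds ratio of 3 between lost and kept peaks, the Mantel-Haenszel ratio averaged 2.99, its interval held the true value in 94 of them, and the unstratified ratio averaged 1.84. Independent lists gave a mean ratio to random placement of 0.997.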

Results

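Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map the binding sites of Smad3, Smad4 and TTF-1 in lung adenocarcinoma cell lines. Smad3 and Smad4 are the transcription factors that carry the TGF-β signal to DNA, and TTF-1 (also called NKX2-1) is the lineage transcription factor of lung epithelium. H441 cells express TTF-1, and A549 cells do not, per the labels. Peak lists of 7 libraries were analysed, 6 from H441 and 1 from A549, and 3 input libraries served as controls for peak calling. The H441 libraries were Smad3 and Smad4 after a control siRNA (siControl) or an siRNA that depletes TTF-1 (siTTF-1), and TTF-1 at 0 h and 1.5 h. The titles of the TTF-1 libraries name no siRNA, and TTF-1 was not mapped in siTTF-1 cells. A siTTF-1 peak with TTF-1 therefore lies at a TTF-1 site of those other cells, and TTF-1 left there after depletion was not measured. The treatment described for the cells was 1 ng/ml TGF-β3 for 1.5 h. Each condition had 1 library, so no difference between conditions could be set against replicate spread, and the depth of the libraries is unknown from the peak lists. All positions are on hg18, counted from 1. The tests below therefore compare peaks within and between these lists, and their intervals cover counting error only.

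The TTF-1 lists were the longest, with 31083 peaks at 0 h and 21291 at 1.5 h. Smad3 had 8941 peaks in siControl cells and 14145 in siTTF-1 cells, and these 4 lists share a false discovery rate limit of 1%. The A549 Smad3 list held 2535 peaks at a limit of 5%. At a limit of 10%, Smad4 had 1605 peaks in siTTF-1 cells and 1 peak in siControl cells. The median peak width was 599 bp for Smad3 in siControl cells and for TTF-1 at 1.5 h and 649 bp in A549 cells, and Smad4 siTTF-1 peaks were narrower, with a median of 299 bp. Together the peaks covered 6.03 Mb for Smad3 in siControl cells, 9.18 Mb for Smad3 in siTTF-1 cells, 19.6 Mb for TTF-1 at 0 h and 14.3 Mb for TTF-1 at 1.5 h.

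**Figure D1:**
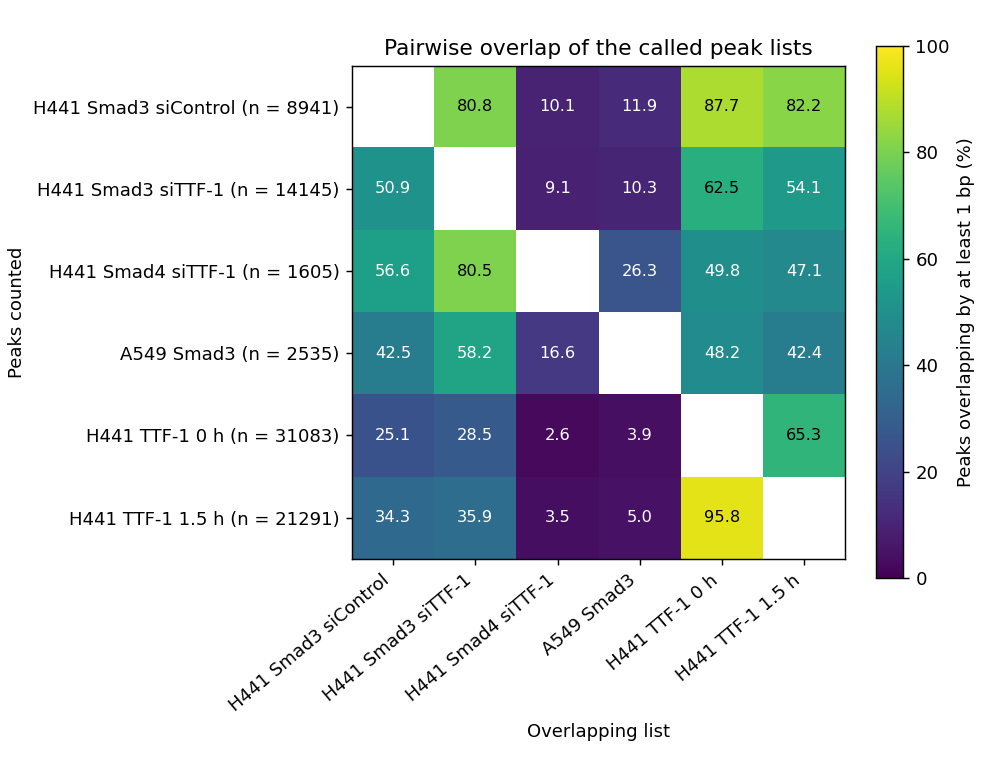
Share of the peaks of each list (rows, with the number of peaks) that overlapped a peak of another list (columns) by at least 1 bp, in percent; the Smad4 siControl list with its 1 peak is left out. Smad3 siControl peaks overlapped TTF-1 peaks more often (82.2% at 1.5 h) than Smad3 siTTF-1 peaks did (54.1%), while the number of such peaks was 7350 in the siControl and 7654 in the longer siTTF-1 list.

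The first comparison asked how Smad3 occupancy in H441 cells relates to TTF-1. Most Smad3 sites of siControl cells were also TTF-1 sites: 7350 of the 8941 peaks (82.2%) overlapped a TTF-1 1.5 h peak. Placing the Smad3 peaks at random on the same chromosomes gave a mean of 86.4 overlapping peaks and at most 115, so the observed number was 85.0 times the mean (permutation of positions, one-sided p = 0.001, the smallest that 1000 placements can give). The ratio was 27.5 when peaks were moved by only 10 to 50 kb, where placed peaks met a TTF-1 peak 266.9 times on average. By random placement, Smad3 peaks of A549 cells, a line without TTF-1, also met H441 TTF-1 1.5 h peaks at 44.2 times the placed mean. A ratio far above 1 is therefore not particular to Smad3 in cells with TTF-1. Overlap with TTF-1 was most frequent at the head of the Smad3 list: when the list was split into 5 equal strata by peak number, 95.9% of the first stratum and 68.1% of the last had a TTF-1 1.5 h peak. The centres of siControl Smad3 peaks that were still called after siTTF-1 lay at a median of 75 bp from the nearest TTF-1 1.5 h centre, against 94016 bp for placed peaks. For those no longer called the median was also 75 bp, against 92963.5 bp for placed peaks. In the other direction, TTF-1 sites with Smad3 were the minority. Smad3 siControl peaks were present at 34.3% of the TTF-1 1.5 h peaks, from 65.8% in the first stratum of the TTF-1 list to 13.9% in the last.

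After TTF-1 depletion, 7223 of the 8941 siControl Smad3 peaks (80.8%, exact binomial 95% interval 79.95 to 81.6) were still called, here named kept, and 1718 were not, here named lost. A further 6944 of the 14145 siTTF-1 peaks had no siControl counterpart and are named gained, so 50.9% (50.1 to 51.7) of the siTTF-1 list was already present in siControl cells. The loss was graded along the list. Of the first stratum of the siControl peaks 96.0% were kept, and of the last stratum 63.7%. The kept share ranged over the chromosomes from 76.3% on X to 85.2% on chromosome 22, and the gained share of siTTF-1 peaks from 42.3% on chromosome 20 to 53.2% on chromosome 2. The nearest siTTF-1 Smad3 centre lay at a median of 25300 bp from lost peaks, against 144327 bp for placed peaks, and 32.3% of the lost peaks had one within 10 kb, against 7.4% of placed peaks. When the siTTF-1 list was shortened to the length of the siControl list by peak number, a choice made after seeing the data, the kept share was 67.1%.

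Lost and gained Smad3 sites differed in their relation to TTF-1. TTF-1 1.5 h peaks were present at 1520 of the 1718 lost sites (88.5%, 86.9 to 89.9), at 80.7% (79.8 to 81.6) of the kept siControl sites and at 1830 of the 6944 gained sites (26.4%, 25.3 to 27.4). Positions 25 kb to either side of the same peaks had a TTF-1 1.5 h peak in 3.1% of cases for lost and kept sites and in 2.1% for gained sites. The odds ratio of TTF-1 overlap was 1.83 (1.56 to 2.15, Fisher's exact test, two-sided p = 3.9e-15) for lost against kept siControl peaks. It was 0.085 (0.078 to 0.092) for gained against kept siTTF-1 peaks. Within 5 strata of peak width the odds ratios were 2.30 (1.96 to 2.71) for lost and 0.087 (0.080 to 0.095) for gained peaks, and within 5 strata of the peak number 3.28 (2.77 to 3.89) and 0.084 (0.077 to 0.093). The ratio for lost peaks turned to 0.89 when peaks had to have centres within 200 bp, and to 0.61 when all lists were shortened to the same number of widest peaks. With strata of the peak number these settings gave 1.10 (0.99 to 1.23) and 0.84 (0.76 to 0.92), so the direction for lost peaks depended on how overlap and lists were defined.

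**Figure D2:**
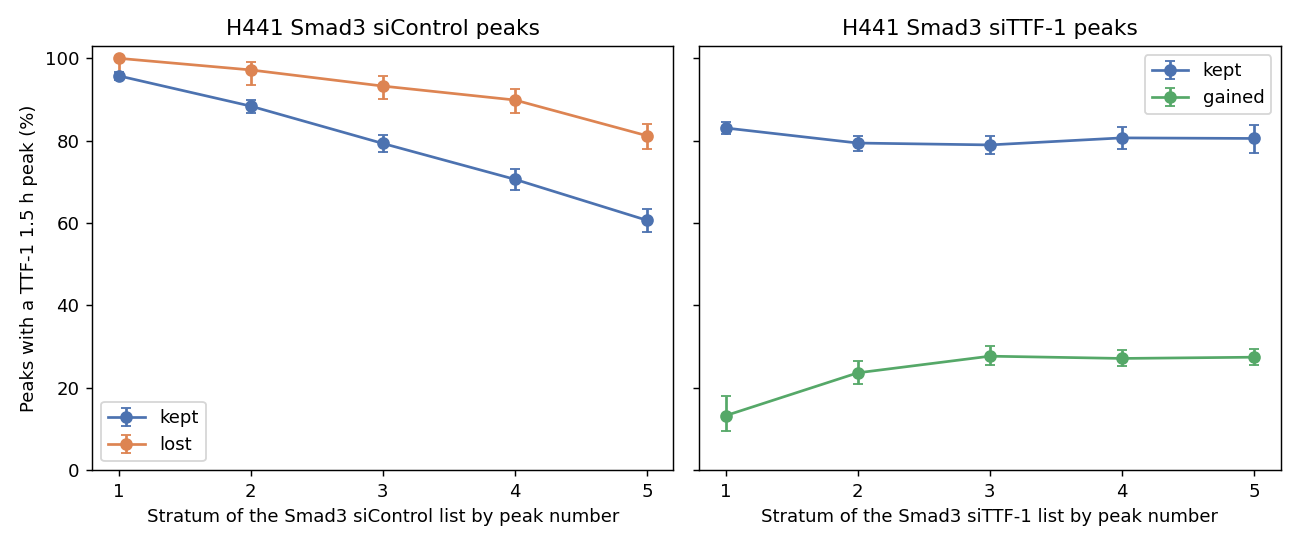
Share of H441 Smad3 peaks with a TTF-1 1.5 h peak, in percent, by 5 equal strata of the Smad3 list in order of peak number (stratum 1 comes first in the list); left, siControl peaks that were kept or lost after siTTF-1, and right, siTTF-1 peaks that were kept from siControl or gained, with points for shares and bars for exact binomial 95% intervals. Kept siTTF-1 peaks lie between 79.0 and 83.1% in all 5 strata, and gained peaks lie between 13.3 and 27.7%.

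All 72 lost peaks in the first stratum had a TTF-1 1.5 h peak, and so did 172 of 177 in the second stratum. Of the 264 gained peaks in the first stratum of the siTTF-1 list, 35 (13.3%, 9.4 to 18.0) had one, against 83.1% of the 2565 kept peaks of that stratum. The first lost peaks by peak number, named after their values were seen, were number 37 (chromosome 1, 58867101 to 58868049), number 179 (chromosome 8, 132909001 to 132910649) and number 254 (chromosome 15, 38523301 to 38523899). All 3 overlapped TTF-1 peaks at both times and none overlapped a Smad4 or A549 peak. The first of them coincided with TTF-1 0 h peak number 3 (58867051 to 58868149). The first gained peaks were number 68 (chromosome 21, 36731951 to 36732699), number 94 (chromosome 4, 8356201 to 8357149) and number 159 (chromosome 1, 226188751 to 226190049). None of these had a TTF-1 peak, and all 3 had a Smad4 siTTF-1 peak. The head of both Smad3 lists was the same kept site on chromosome 5, at 135383451 to 135384749 in siControl cells, which also had TTF-1 peaks at both times, a Smad4 siTTF-1 peak and an A549 peak.

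The 3 widest kept siControl peaks were a 6699 bp peak on chromosome 14 (36054751 to 36061449), a 5999 bp peak on chromosome 12 (12761501 to 12767499) and a 5849 bp peak on chromosome 3 (4998801 to 5004649). All 3 had a TTF-1 0 h peak, and the first also had one at 1.5 h. The widest peak of the siTTF-1 list, 10599 bp on chromosome 11 (65021451 to 65032049), had TTF-1, Smad4 siTTF-1 and A549 peaks. The next widest kept siTTF-1 peaks, of 8049 bp on chromosome 3 (4996601 to 5004649) and 5349 bp on chromosome 12 (50923101 to 50928449), had a TTF-1 0 h peak. The 3 widest lost peaks had no TTF-1 peak. They lay on chromosome 17 (76931301 to 76933449), chromosome 12 (12767651 to 12769549) and chromosome 5 (43076301 to 43078099), at peak numbers 4546 to 6155, and the second lay beside the wide kept peak on chromosome 12. The 3 widest gained peaks lay on chromosome 17 (7685351 to 7688499), chromosome 20 (56025401 to 56027949) and chromosome 22 (29148701 to 29150949), and the first of these had a TTF-1 0 h peak. The 1 Mb windows with the most siControl Smad3 peaks were 3000001 to 4000000 on chromosome 10, with 22 peaks and 33 after siTTF-1, and 8000001 to 9000000 and 59000001 to 60000000 on chromosome 1, with 19 each.

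Lost sites were almost free of the other Smad peaks. Smad4 siTTF-1 peaks were present at 6 of the 1718 lost sites (0.35%, 0.13 to 0.76), at 12.4% (11.7 to 13.2) of the kept siControl sites and at 5.5% (5.0 to 6.1) of the gained sites. The share at positions 25 kb from the lost peaks was 0.087%. A549 Smad3 peaks were present at 19 lost sites (1.1%, 0.67 to 1.7), at 14.5% (13.7 to 15.4) of the kept siControl sites and at 5.9% (5.4 to 6.5) of the gained sites. Lost against kept, the odds ratio was 0.025 (0.011 to 0.055, Fisher's exact test, two-sided p = 1.3e-77) for Smad4 and 0.066 (0.042 to 0.104, p = 7.9e-77) for A549. Within 5 strata of the peak number both remained below 1, at 0.036 (0.016 to 0.081) and 0.089 (0.056 to 0.141), and with centres within 200 bp they were higher, at 0.33 (0.26 to 0.43) and 0.35 (0.28 to 0.44). Gained against kept siTTF-1 peaks, the Smad4 odds ratio was 0.41 (0.36 to 0.47) without strata, 0.69 (0.60 to 0.79) within 5 strata of width and 1.31 (1.12 to 1.54) within 5 strata of the peak number, so its direction turned with the strata. For A549 the same ratios were 0.37 (0.33 to 0.42), 0.57 (0.51 to 0.65) and 0.76 (0.66 to 0.88). Since the Smad4 list comes from siTTF-1 cells, as does the Smad3 list that defines loss, these 2 lists share their condition. Most Smad4 siTTF-1 peaks (1292 of 1605) overlapped a Smad3 siTTF-1 peak, so a low Smad4 share at lost sites largely follows from the definition of loss. The Smad4 p-value therefore adds little. The Smad4 siControl list, with 1 peak, cannot show whether Smad4 was at these sites in siControl cells.

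**Figure D3:**
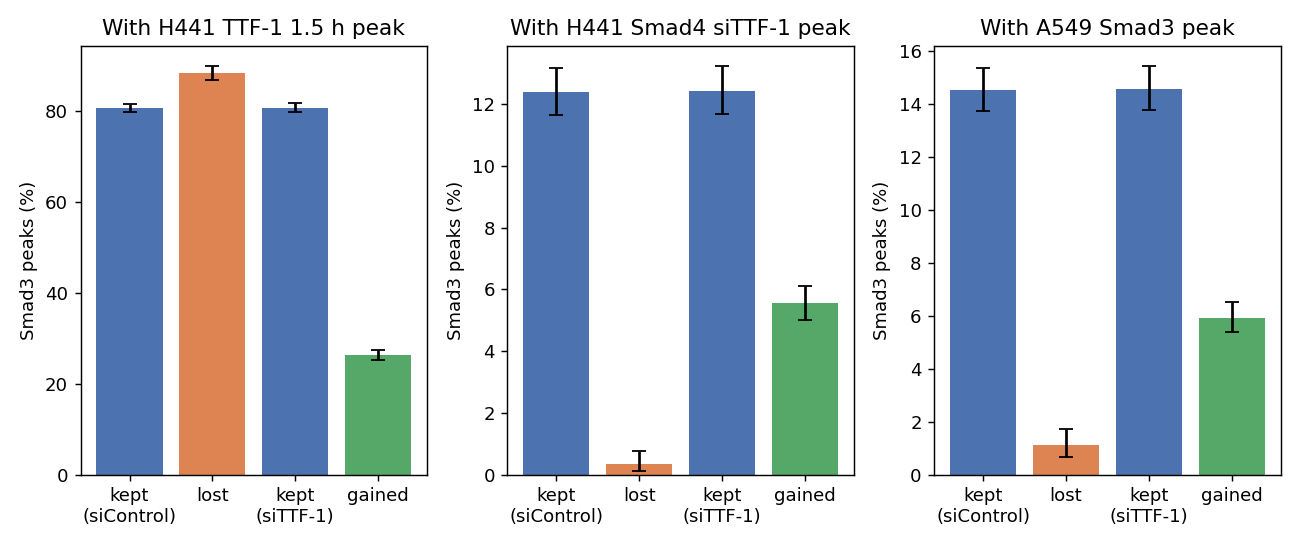
Share of H441 Smad3 peaks, in percent, that overlap a TTF-1 1.5 h, a Smad4 siTTF-1 or an A549 Smad3 peak, for siControl peaks kept or lost after siTTF-1 and for siTTF-1 peaks kept from siControl or gained; bars are shares with exact binomial 95% intervals, and each panel has its own axis from 0. Lost peaks have the highest TTF-1 share (88.5%) and the lowest Smad4 (0.35%) and A549 (1.1%) shares.

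Lists split by TTF-1 were deposited with the series. The lost set of 1718 peaks and the siTTF-1 Smad3 peaks with (8847) and without (5298) a TTF-1 0 h peak were recovered peak for peak with a 1 bp overlap. Smad4 siTTF-1 peaks were present at 783 of the 8847 Smad3 sites with a TTF-1 0 h peak (8.9%, 8.3 to 9.5) and at 498 of the 5298 sites without (9.4%, 8.6 to 10.2). No difference was detected (odds ratio 0.94, 0.83 to 1.05, Fisher's exact test, two-sided p = 0.28). The Smad3 sites with TTF-1 stood earlier in the list, at a median peak number of 6004 against 8704. Within 5 strata of peak width the odds ratio was 0.66 (0.59 to 0.75), and within 5 strata of the peak number it was 0.52 (0.46 to 0.59). In the first stratum, Smad4 peaks were present at 23.3% of the Smad3 sites with TTF-1 and at 36.6% of those without. The widest Smad3 sites without TTF-1 0 h were a 4499 bp peak on chromosome 19 (12760001 to 12764499), a 3099 bp peak on chromosome 20 (55701351 to 55704449) and the wide gained peak on chromosome 20 named above, and all 3 had an A549 peak. With the TTF-1 1.5 h list in place of the 0 h list the unstratified ratio was 1.19 (p = 0.003 by the same exact test).

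The Smad4 libraries asked how Smad4 occupancy relates to TTF-1. The only siControl peak lay on chromosome 1 at 79069801 to 79070299. It overlapped a peak of every other called list, among them number 9 of the Smad4 siTTF-1 list and number 347 of each H441 Smad3 list. Of the 1605 Smad4 siTTF-1 peaks, 1292 (80.5%, 78.5 to 82.4) overlapped a Smad3 siTTF-1 peak and 909 (56.6%, 54.2 to 59.1) a Smad3 siControl peak. Positions 25 kb away overlapped a Smad3 siTTF-1 peak in 1.3% of cases. With the Smad3 siTTF-1 list shortened to 1605 peaks, the share of Smad4 peaks that overlapped it was 26.0% by width and 34.2% by peak number. A total of 902 peaks met both Smad3 lists, 390 only the siTTF-1 list and 7 only the siControl list. TTF-1 0 h peaks were present at 75.9% (73.0 to 78.7) of the Smad4 sites with both Smad3 lists, at 22.3% (18.3 to 26.8) of those with Smad3 only after siTTF-1, and at 7.2% (4.6 to 10.7) of the 306 sites with neither. The widest Smad4 peaks with Smad3 lay on chromosome 20 (56025701 to 56026649), chromosome 13 (35363851 to 35364699) and chromosome 1 (226188901 to 226189699); the first and the third sat in gained Smad3 peaks. Without Smad3 the greatest width was 449 bp, and the first 3 peaks of that width in chromosome order lay on chromosomes 3 (197076451), 7 (84853601) and 9 (46986151). A peak on chromosome 15 (37542101 to 37542549), at number 67, had the same width. The 1 Mb window with the most Smad4 peaks, 10, was 169000001 to 170000000 on chromosome 4, which also held the most Smad3 siTTF-1 peaks (35, against 17 in siControl cells). The difference between 1 and 1605 peaks has no replicate check.

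The TTF-1 libraries compared TTF-1 occupancy at 0 h and 1.5 h. These times come from the sample titles, while the treatment label gives 1.5 h of TGF-β3 for both libraries, so that 0 h means untreated is an inference from the title. TTF-1 was found at largely overlapping sites at both times: 20399 of the 21291 peaks at 1.5 h (95.8%, 95.5 to 96.1) were also called at 0 h. Of the 31083 peaks at 0 h, 65.3% (64.8 to 65.8) were also called at 1.5 h, against 2.4% of positions 25 kb away. The missing peaks stood late in the 0 h list. In its first stratum, 6215 of 6217 peaks were called again, in the last stratum 16.7%. The 10780 peaks called only at 0 h had a Smad3 siControl peak in 6.4% of cases, and the 20303 kept peaks in 35.0% (34.4 to 35.7); the odds ratio was 0.127 (0.117 to 0.138), and 0.27 (0.24 to 0.30) within 5 strata of the peak number. The widest kept TTF-1 peaks lay on chromosome 3 (158327651 to 158331549), chromosome 10 (5577751 to 5581499) and chromosome 14 (61060601 to 61064049), and all 3 had Smad3 peaks in both conditions. The widest peaks called only at 0 h lay on chromosome 22 (35058251 to 35060049), chromosome 10 (75317651 to 75319349) and chromosome 12 (13266401 to 13267999) at peak numbers 28996, 28261 and 25038. The widest called only at 1.5 h lay on chromosome 7 (92233501 to 92234849), chromosome 1 (184998301 to 184999499) and chromosome 16 (65104551 to 65105699), and all 3 had a Smad3 siTTF-1 peak. TTF-1 peaks were densest at 0 h in 2 windows of 44 peaks, at 205000001 to 206000000 on chromosome 1 and 178000001 to 179000000 on chromosome 3. At 1.5 h they were densest in 2 windows of 35 peaks, at 83000001 to 84000000 on chromosome 9 and 68000001 to 69000000 on chromosome 15.

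**Figure D4:**
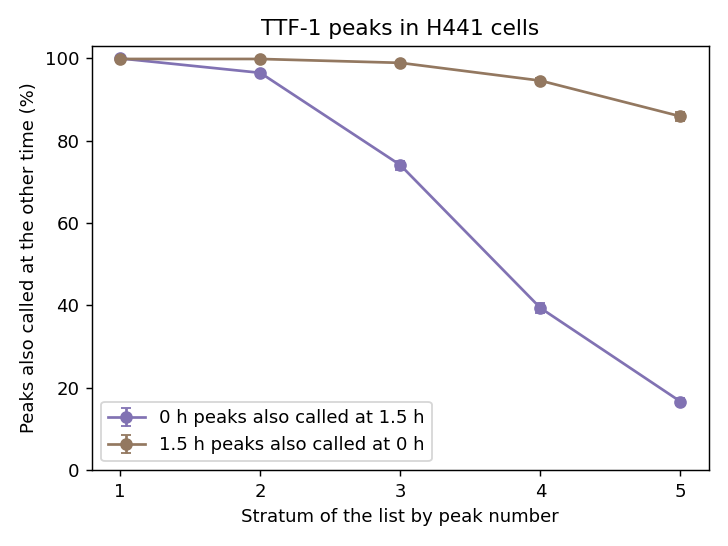
Share of TTF-1 peaks in H441 cells that were also called at the other time, in percent, by 5 equal strata of each list in order of peak number (stratum 1 comes first in the list); points are shares and bars exact binomial 95% intervals, most of them smaller than the points. The share of 0 h peaks called again falls to 16.7% in the last stratum, and the share of 1.5 h peaks found at 0 h stays at 85.9% or more.

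A549 cells gave Smad3 sites in a line without TTF-1. Of the 2535 A549 Smad3 peaks, 1078 (42.5%, 40.6 to 44.5) overlapped a Smad3 peak of H441 siControl cells and 1476 (58.2%, 56.3 to 60.2) one of H441 siTTF-1 cells. Positions 25 kb away did so in 1.2% and 1.9% of cases. Peaks found only in the siTTF-1 list numbered 419 and peaks found only in the siControl list 21, a difference of 15.7 percentage points (exact McNemar test, two-sided p = 2.9e-97). The siTTF-1 list is the longer one. Shortened to the siControl length by peak number it held 49.8% of the A549 peaks, and the difference was 7.26 points (254 against 70 peaks, exact p = 1.2e-25). With all 3 lists shortened to the 2535 widest peaks the shares were 22.6% in siControl and 26.1% in siTTF-1, and the difference was 3.55 points (exact McNemar p = 1.0e-06). Shortened to the first 2535 by peak number, the lists gave 20.9% and 26.0%.

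A549 peaks outside the H441 Smad3 lists numbered 1038 (40.9%, 39.0 to 42.9), and 14.1% (12.0 to 16.3) of them had an H441 TTF-1 0 h peak. The share was 71.8% (69.5 to 74.1) for the 1497 A549 peaks with an H441 Smad3 peak. TTF-1 0 h peaks were present at 36.5% (31.9 to 41.3) of the A549 sites found only after siTTF-1 and at 85.3% (83.1 to 87.4) of those found in both H441 lists. Seen from H441, A549 peaks were present at 11.7% (10.9 to 12.4) of the siControl Smad3 sites with TTF-1 1.5 h and at 13.3% (11.6 to 15.03) of those without (odds ratio 0.86, 0.73 to 1.01, Fisher's exact test, two-sided p = 0.080). Within 5 strata of peak width this ratio was 0.65 (0.55 to 0.77) and within 5 strata of the peak number 0.53 (0.44 to 0.63). The siTTF-1 Smad3 list ran the other way, with A549 peaks at 11.8% (11.2 to 12.5) of the sites with TTF-1 0 h and at 7.8% (7.1 to 8.6) of those without. Its odds ratio was 1.59 (1.41 to 1.79), and 1.22 (1.07 to 1.38) within strata of width and 1.10 (0.97 to 1.25) within strata of the peak number. The widest A549 peaks shared with H441 Smad3 lay on chromosome 15 (60974201 to 60977099), chromosome 3 (5002301 to 5004499) and chromosome 12 (116407951 to 116410099). The widest without an H441 Smad3 peak lay on chromosome 5 (168709401 to 168711449), chromosome 9 (21547301 to 21549299) and chromosome 12 (109030151 to 109032149), and the last of these had TTF-1 peaks in H441. The A549 window with the most peaks, 18, was 21000001 to 22000000 on chromosome 9, where the H441 Smad3 lists held 7 and 8.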

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

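The alternatives that use the peak number were chosen after seeing the data, and the others before the data were examined. Of 160 alternative values, 80 stayed within their interval or on their side of the threshold, 14 peak counts stayed within 1.5 times the main count, 47 shares moved beyond their counting interval, 14 odds ratios passed the threshold of 0.05 that they had missed, 1 no longer passed it and 4 reversed. The ratio of observed to placed overlap of Smad3 with TTF-1 (27.5 to 247.3) and the lower TTF-1 odds of gained peaks kept their direction and call under every alternative run. No interval is widened for the depth of the libraries, which is unknown, and no condition has a second library.

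The odds ratio of TTF-1 overlap for lost against kept Smad3 peaks reversed to 0.89 with centres within 200 bp (Fisher's exact p = 0.035). It reversed to 0.61 in lists of equal length by width, where narrow peaks leave the TTF-1 and siTTF-1 lists and so change which peaks count as lost. With strata of the peak number added it was 1.10 with centres within 200 bp, no longer past the threshold, and reversed to 0.84 in lists of equal length by width. In these strata it stayed above 1 when only 1 of the rules changed: at 1.82 for the TTF-1 rule and 2.12 for the rule of loss with centres within 200 bp, and at 2.52 with the TTF-1 list and 2.09 with the siTTF-1 list shortened by width. The Smad4 odds ratio of Smad3 siTTF-1 peaks with against without TTF-1 reversed to 1.19 with the TTF-1 1.5 h list, and the cause was not tested. It passed the threshold at 0.47 with 50% coverage, 0.66 within 5 strata of width, 0.76 in the wider 50% of each list, 0.62 in lists of equal length by width, 0.85 in the first 50% by peak number, 0.72 in lists of equal length by peak number and 0.52 within 5 strata of the peak number. The A549 odds ratio of siControl Smad3 peaks with against without TTF-1 passed it at 0.75 with 50% coverage, 0.84 on autosomes, 0.78 with the TTF-1 0 h list, 0.65 within 5 strata of width, 0.61 in the first 50% by peak number, 0.57 in lists of equal length by peak number and 0.53 within 5 strata of the peak number. Why these passed was not tested.

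In the order kept after siTTF-1, already in siControl, TTF-1 0 h peaks at 1.5 h, TTF-1 1.5 h peaks at 0 h, A549 peaks in siControl and A549 peaks in siTTF-1, the shares were 79.1, 48.9, 63.7, 95.2, 39.8 and 55.1% with 50% coverage, 74.7, 47.2, 62.4, 91.1, 33.7 and 46.5% with centres within 200 bp, 76.9, 48.5, 63.9, 93.5, 39.8 and 54.5% in the wider 50% of each list, and 61.7, 61.1, 78.3, 79.0, 22.6 and 26.1% in lists of equal length by width. In lists of equal length by peak number they were 67.1, 66.5, 85.0, 85.8, 20.9 and 26.0%. In the first 50% by peak number the shares that moved were 78.4% kept, 49.4% already in siControl, 95.5% of the 1.5 h peaks at 0 h, and 36.4 and 51.7% of the A549 peaks. With edges within 500 bp the shares that moved were 81.8% kept, 52.5% already in siControl, and 67.0 and 96.4% for TTF-1. With peaks merged, those for TTF-1 were 65.9 and 96.1%. With only the siTTF-1 list shortened by peak number to the siControl length, the shares were 67.1% kept, 66.5% already in siControl and 49.8% of the A549 peaks. The share of Smad4 siTTF-1 peaks with Smad3 siTTF-1 was 65.7% with centres within 200 bp, 26.0% in lists of equal length by width and 34.2% by peak number. The planned counts of gene lists near peaks and of motifs were not run.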

Other observations

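Some tests were chosen only after the result was seen. Among them were those of the chromosome 15 cluster, of gained against lost peaks in A549, and of the share of first 0 h peaks missing at 1.5 h. So were those of lost peaks with only 1 list or rule changed and of strata combined with another overlap rule or list length. A549 overlap of lost peaks under other settings was also examined only then. All strata of the peak number were chosen after the data were examined.

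TTF-1 peaks called only at 1.5 h were few, 892 of 21291, and 34.3% (31.2 to 37.5) of them had a Smad3 siTTF-1 peak and 19.7% (17.2 to 22.5) a Smad3 siControl peak. The TTF-1 1.5 h peaks also called at 0 h had these in 35.9% and 34.9% of cases. Within 5 strata of the peak number the odds ratio, 1.5 h only against the others, was 1.53 (1.32 to 1.78) for Smad3 siTTF-1 and 1.24 (1.04 to 1.48) for Smad3 siControl; without strata they were 0.93 (0.81 to 1.07) and 0.46 (0.39 to 0.54), and within 5 strata of width 1.32 (1.14 to 1.53) and 0.82 (0.69 to 0.97), so both depended on the strata. Smad4 siTTF-1 peaks were present at 5.4% (4.0 to 7.1) of the 1.5 h only peaks and at 3.5% of the others. Of the siControl Smad3 sites found also in the Smad3 siTTF-1, Smad4 siTTF-1 and A549 lists, 349 in number, 75.9% (71.1 to 80.3) had a TTF-1 1.5 h peak. Chromosome 20 held 4.18% of the A549 Smad3 peaks and 2.82% of the H441 siControl Smad3 peaks, chromosome 4 held 3.71% and 6.05%.

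The Smad3 lists differed in length and in their relation to TTF-1. A more sensitive siTTF-1 library would add sites past the end of the siControl list, whose TTF-1 share is not known. In the last stratum of that list 68.1% (65.9 to 70.3) had a TTF-1 1.5 h peak, down from 95.9% in the first. Gained peaks in the first stratum of the siTTF-1 list had one in 13.3% (9.4 to 18.0) of cases, and kept peaks of that stratum in 83.1%. In the last stratum the shares were 27.4% and 80.5%. This gap at like peak numbers argues against sensitivity as the whole cause. That lost sites are only weak peaks near the calling limit is argued against as the whole cause only while the rules for loss and for TTF-1 are not both changed. With 1 bp for both, the TTF-1 odds ratio, lost against kept within 5 strata of number, was 3.28 (2.77 to 3.89). With loss at 1 bp it lay between 1.44 and 4.80 (lowest lower bound 1.26) under every TTF-1 list and overlap rule run. With TTF-1 at 1 bp it lay between 2.09 and 3.39 (lowest lower bound 1.84) under every other rule of loss run. Lost peaks did stand later (median number 6445.5 against 3921) and were narrower (499 against 649 bp). With both rules changed the ratio was 1.10 (0.99 to 1.23) with centres within 200 bp and 0.84 (0.76 to 0.92) in lists of equal length by width. There 542 and 1708 peaks that do overlap a siTTF-1 peak count as lost. Changing the rule of loss alone counted the same peaks as lost and gave 2.12 and 2.09, so they do not by themselves account for the lower ratios. The direction of the TTF-1 ratio therefore depended on the definitions, and that ratio does not settle the question across them. A549 overlap kept its direction. Lost against kept in strata of number, its odds ratio was 0.35 (0.28 to 0.44) with centres within 200 bp. With the siTTF-1 list of equal length by width it was 0.15 (0.12 to 0.19). Lost peaks in the first 2 strata had an A549 peak in 2 of 249 cases (0.80%), against 8.8% of kept peaks in the last stratum. These lost peaks were thus unlike the latest kept ones, but this rests on 1 A549 library. By the bound set before this test was run, but in strata chosen after the data were examined, gained sites did not resemble the Smad3 sites of A549 cells. The odds ratio of A549 overlap against kept peaks in strata of number was 0.76 (0.66 to 0.88), with its upper bound below 1. That bound used kept peaks alone, which are in both H441 lists by definition. Against lost peaks, a comparison chosen after the result was seen, the ratio was 5.63 (3.54 to 8.94) without strata. Lost peaks had the lowest A549 share (1.1%). The answer thus depended on the class compared and stays open. Smad3 peaks with a TTF-1 1.5 h peak numbered 7654 after siTTF-1 and 7350 in siControl cells. The lists differ in length and their depth is unknown, so these counts neither show nor exclude a net move of Smad3 away from TTF-1 sites. By strata of number the share was lower in the siTTF-1 list, from 76.6% against 95.9% in the first to 37.9% against 68.1% in the last. Loss of Smad3 at some TTF-1 sites and gain at other sites when TTF-1 is depleted may underlie the pattern. So may another difference between the 2 single libraries, which no replicate separates from it.

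Fewer TTF-1 peaks were called at 1.5 h. Of the first stratum of the 0 h peaks 0.032% (2 of 6217) were missing at 1.5 h, so the missing peaks stand late in the list, as lower sensitivity of the 1.5 h library would give. Departure of TTF-1 from the sites that Smad3 occupies left no sign in the calls. The 0 h only peaks had Smad3 siControl peaks less often (odds ratio 0.27, 0.24 to 0.30, within 5 strata of the peak number). The test cannot exclude departure, however. Smad3 siControl peaks were present at 56.3% of the first stratum of the 0 h list and at 8.4% of the last. Sites with Smad3 thus stood early, where few calls were missing, and a call cannot show a weaker signal there. A general weakening of TTF-1 binding between 0 h and 1.5 h may also fit these values and stays open as untested.

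The head of the TTF-1 1.5 h list held a cluster that no other list showed, found by looking through the peaks called only at 1.5 h. On chromosome 15, 7 peaks lay within 9.60 kb (41264951 to 41274549) with peak numbers 1, 2, 21, 51, 63, 247 and 602, the 7 lowest-numbered of the 892 peaks called only at 1.5 h (the next was number 4947), and no other 20 kb window held more than 2 such peaks. None of the 7 had a Smad3 peak (0%), against 84.5% (81.4 to 87.3) of the 595 other TTF-1 1.5 h peaks up to number 602, but 7 peaks of 1 locus are 1 observation, and their absence from the other lists was part of what was noticed, so TTF-1 recruited together with Smad3 stays open. DNA from outside the ChIP, such as cloned DNA, in the 1.5 h library is a candidate explanation that also stays open, since a test needs the exons of hg18, which were not used here.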
